A study of Populus tremula with 16 samples.

How the data were processed

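Leaves of Populus tremula (European aspen) were collected on 16 dates from 27 July to 1 October 2011, and 1 RNA sequencing library was made per date. Per the labels' protocols, total RNA was extracted and cleaned on a silica column kit, and libraries were prepared with the Illumina TruSeq RNA kit. The labels do not say whether the leaves came from 1 tree or from several, or whether leaves were pooled. Dates therefore stood in for replicates, and p-values measure only the scatter of single dates, which holds change from day to day as well as technical error.

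The authors deposited raw read counts per gene ID for 41335 IDs. Per the submitters' processing notes, CASAVA 1.8.2, FastQC 1.0, Trimmomatic 1.0, STAR 2.4 (the aligner) and HTSeq (the read counter) were used, without a stated role or order. The genome build, the annotation version, the HTSeq version, the strand setting and the treatment of reads with several matching places are not given in the sources used here. The 16 single library tables are named as log values but held whole counts identical to those of the joint raw table, so they were read as counts. Every row named a gene ID that begins with Potri, so no unassigned reads entered the library totals. How well P. tremula reads match the reference behind these IDs was not checked, and levels of single IDs are uncertain to that extent.

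The authors also deposited a normalised table, a signal in which each count was divided by 1 factor per library, for 19769 of the IDs. Multiplied by that factor, 99.98% of its values came out as the raw count within 0.01. Computed over those IDs and all 16 libraries, edgeR's effective library sizes by the trimmed mean of M values (TMM) matched the factors within 8.5e-06%, which was inferred from the values and is not stated in the labels. Of the 21566 IDs left out of that table, 11036 had no count in any library. The main tests used the raw counts.

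Library totals ranged from 719419 to 6729131 counts. Outside the 10 most abundant IDs, 164929 to 1191612 counts per library remained, and the median count over the 19769 IDs ranged from 3 to 22. A count of 0 allows up to 3 counts, which is 0.61 to 3.76 CPM per library (counts scaled to a common library size by TMM). Confidence intervals of shares are 95% Wilson intervals, and those of ratios of summed counts are exact binomial intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

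Libraries were compared in all 120 pairs before any averaging, by the scatter of counts about the pair's common proportion over binomial sampling, for IDs with 20 to 1999 counts in the pair. The libraries of 18 and 19 September differed by less than sampling noise and were counted as 1 library. Every count of 19 September was equal to or below that of 18 September, so the deeper counts of 18 September were used in place of a mean or a sum, and 15 libraries entered the fits. The design fixed before the data were examined had all 16 libraries, and the values with all 16 are given in the closing section.

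The dates were divided into July and August (n = 4), 1 to 15 September (n = 6) and 16 September to 1 October (n = 5 after the merge). The labels give only the dates, and these periods were set from the calendar before the data were examined. They are called early, middle and late here. IDs were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15583 IDs, and libraries were scaled by TMM. The period contrasts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest) in 1 fit of all 15 libraries, and the time course with a natural cubic spline of the day with 3 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change over the root of the F statistic. Neighbouring dates resemble each other, which makes the p-values of these tests too small.

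Called IDs of the time course were grouped by their fitted curve, a choice made after the data were examined. A net rise or fall was at least 75% of the curve's range, and the others were split by whether the larger excursion beyond the ends was a peak or a trough. Principal components were computed from log2 CPM (prior count 2) of the 500 most variable IDs, with 100000 permutations of the days. The 10 most abundant IDs were ranked by their summed counts over the 16 libraries, and the 10 highest IDs of each library were used as a comparison chosen after the data were examined. Single measures per library were compared between periods by two-sided exact permutation tests of the means, 18 tests in 1 family, also chosen after the data were examined. Each period is a run of neighbouring dates, so any steady drift over the dates gives small p-values in these tests too. For measures that move with depth, each library was thinned at random to 164929 counts outside the 10 most abundant IDs.

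Counts were simulated from each ID's mean level, the dispersions of the period fit and the real library sizes. In each simulation 200 of 15583 IDs were changed. The late against early test recovered 6 of 67 changes of 2-fold, 52 of 67 of 4-fold and 59 of 66 of 8-fold, with 9 false calls. The time course test, simulated with a straight change over the days on the log scale, recovered 0 of 67, 3 of 67 and 32 of 66, with 2 false calls. Dispersions of the period fit hold change within periods, which the spline models. The time course recoveries therefore cannot measure the sensitivity of the real time course test. The Benjamini-Hochberg threshold is stricter when few IDs change, and the real late against early test called 9068 IDs. The late against early recoveries therefore do not give the sensitivity of that real test either. Simulated libraries were independent, so the false calls do not cover the likeness of neighbouring dates.

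The deposited tables do not pair the IDs with gene names, and no annotation was used here. The 32 gene lists fixed before the data were examined are defined by names, so none of them could be matched and no gene list was tested. The rule for named features then allowed 2 IDs that rose and 2 that fell from early to late. They had to pass the threshold, have an average log2 CPM of at least 3 and have no overlap of libraries between the periods, and the largest fold changes were taken. Under that rule 2318 IDs qualified as higher and 1484 as lower. Without strand or annotation, counts of near-identical copies, overlapping genes and antisense genes cannot be separated, so values of single IDs are uncertain to that extent.

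Alternatives fixed before the data were examined were other scalings (relative log expression, upper quartile and library totals), other filters on low counts, DESeq2 1.42.0, limma-voom and limma 3.58.1 on log2 of the authors' normalised values plus 0.5. They also covered other spline degrees, shifted period limits, stricter thresholds and leaving out each library in turn. Alternatives chosen after seeing the data were all 16 libraries, 19 September in place of 18 September, leaving out the 4 libraries with the lowest totals (11, 15 and 28 September and 1 October), leaving out 28 September and 1 October, thinning to 1 depth and removal of the 10 most abundant IDs. Fits of the middle period with 1 other period alone, and an exchange of the dates of 2 and 5 September, were also chosen after seeing the data.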

Results

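RNA of aspen leaves was sequenced on 16 dates over 66 days of late summer and autumn 2011, to follow gene expression through autumn senescence, the ordered breakdown of the leaf before it is shed. There was 1 library per date, and the dates were divided into an early period of July and August (n = 4), a middle period of 1 to 15 September (n = 6) and a late period of 16 September to 1 October (n = 6). Early libraries held 5962319, 6729131, 6008349 and 5148979 counts on 27 July and on 5, 19 and 31 August. Middle libraries held 4609652, 5954322, 4477500, 719419, 2449021 and 836643 counts on 2, 5, 9, 11, 13 and 15 September. Late libraries held 4344936, 1034872, 3789246, 3271054, 1162665 and 756966 counts on 18, 19, 22, 26 and 28 September and 1 October. Gene features are given as the IDs of the deposited tables, which do not pair them with gene names.

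The libraries of 18 and 19 September differed by less than the sampling noise and were counted as 1 sample, so the late period had n = 5. The scatter between them was 0.618 times that of binomial sampling, and the lowest value in the other pairs was 1.82. Of 18378 IDs with a count on 19 September, 0 had more counts there than on 18 September.

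Along its main axis of variation, leaf expression moved with the calendar, slowly at first and then fast. The first principal component of the 500 most variable IDs held 86.8% of their variance, and libraries from 27 July to 31 August stayed within the lowest 2.91% of its range. Middle libraries lay between 9.43% and 24.6% of the range. Late libraries lay at 41.3% on 18 September, 50.9% on 22 September, 66.7% on 26 September, 95.7% on 28 September and 100% on 1 October. The component rose with the day with Spearman's rho of 0.97 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Pearson's r of 0.80 (permutation p = 0.001), as 2 statistics of 1 relation. Without the 2 dates farthest from the median day, rho was 0.96 and r was 0.88. Neighbouring dates are not independent, so these p-values are too small. Over all tested IDs, the early libraries did not follow the date order. Their rank correlation with 27 July was 0.875 on 5 August, 0.943 on 19 August and 0.889 on 31 August, against 0.195 on 1 October. The root mean square log2 step from the library before was 0.71, 0.69 and 0.62 on these August dates. It was 0.52 on 22 September and 1.09 on 28 September, and such steps include counting noise.

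**Figure D1:**
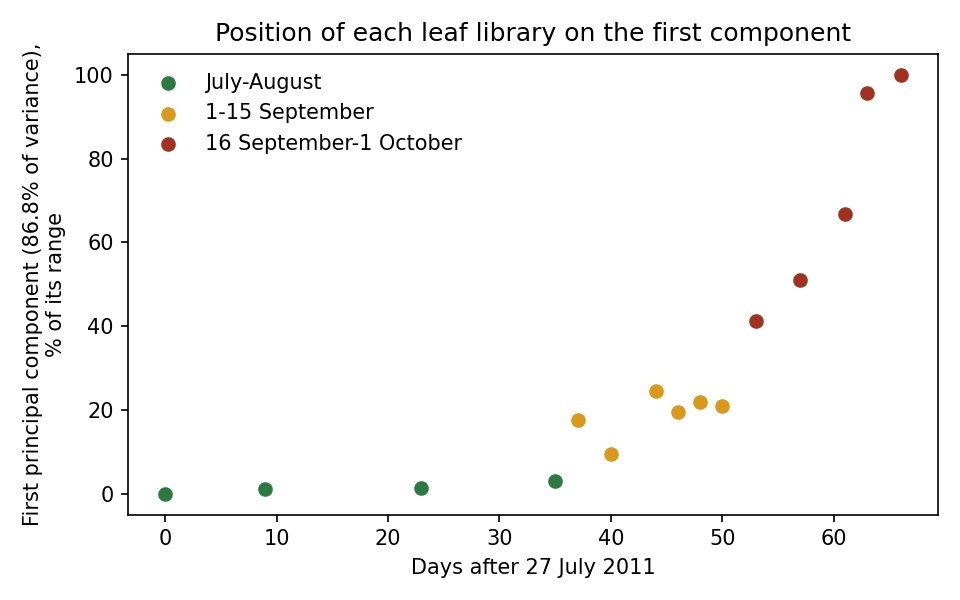
Position of each of the 15 libraries on the first principal component, as a percentage of its range (y axis), against days after 27 July 2011 (x axis), with 1 point per library coloured by period. Early libraries lie within 2.91% of the range, and the late ones climb from 41.3% to 100%.

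Over the whole time course, 9807 of 15583 tested IDs (62.9%) changed with the day, by edgeR's quasi-likelihood test at an adjusted p of 0.05. Net rises were fitted for 3917 IDs and net falls for 4298 IDs. Both groups changed late on the log2 scale. The median day by which 50% of the net log2 change had passed was day 57, which was 22 September, for risers and for fallers. For risers the quartiles of that day were 50 and 59, and for fallers they were 54 and 59. After day 53, 18 September, that point was passed by 65.5% of the risers and 77% of the fallers. On a linear scale the point would come later for risers and earlier for fallers, so equal timing was not shown there. A smaller group of 853 IDs peaked inside the series, at a median day of 48, and 739 IDs had a trough inside it, at a median day of 41. The median fitted range was 2.89 log2 units for risers, 3.14 for fallers, 1.95 for peaks and 1.94 for troughs. These groups were formed after the curves were seen, and the spline smooths over single dates.

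Between the early and the late leaves, 9068 IDs (58.2% of those tested) differed, 4559 higher and 4509 lower in the late leaves, by edgeR's quasi-likelihood test. Among them, 3740 rose and 3967 fell by more than 2-fold, and 1081 rose and 615 fell by more than 8-fold. The libraries of both periods did not overlap for 46% of the tested IDs, where chance gives 1.59% if every division of the libraries is equally likely. Each period is a run of neighbouring dates, so any drift over the dates raises that share. The split depended on the scaling, and the share of higher IDs among the calls was 50.3% with TMM, 45% with relative log expression, 40.8% with the upper quartile and 79.5% with library totals alone. The median log2 change of all tested IDs was 0.01, -0.12, -0.24 and 0.92 under these scalings, so the directions given here are relative to the TMM reference.

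Of the 2318 higher IDs that met the rule for naming, Potri.003G213700 and Potri.003G216600 were taken by their fitted changes. Fitted changes from 0 counts are uncertain, and with period limits 1 date later their order turned, with 9.29 and 12.85 log2 units. Potri.003G213700 had 0 counts in the 4 early libraries and 2896 counts in the late ones. Its level was 0 CPM early, 3.86 ± 2.97 CPM in the middle period (SD, n = 6) and 305 ± 304 CPM late (SD, n = 5). By summed counts, which gave 180 CPM late, late leaves had at least 949-fold more, against a floor of 3 counts over the early period (edgeR adjusted p = 1.96e-05). Within the late period it climbed from 42.7 CPM on 18 September to 644 CPM on 1 October. Potri.003G216600 had 0 early counts, 1 middle count and 1721 late counts. By summed counts, 107 CPM late, it was at least 564-fold higher late than early (edgeR adjusted p = 0.000156). Its late libraries ran from 1.45 CPM on 18 September through 67.1 CPM on 26 September to 611 CPM on 1 October. Without 1 October the bound was 357-fold. The bounds of both IDs allow for the 0 early counts, not for the spread of their late libraries.

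Of the 1484 lower IDs that met the rule, Potri.001G348900 was taken in the same way and stood at 398 ± 211 CPM early (SD, n = 4), 2.99 ± 4.16 CPM in the middle period (SD, n = 6) and 0.0414 ± 0.0927 CPM late (SD, n = 5). Summed counts were 6443, 78 and 1, a ratio of early to late of 6555 after scaling, with a 95% exact interval of 1176 to 258958 that covers counting error only. The late count came from 18 September, and without that library the fall was at least 1530-fold. Without 5 September its middle mean was 1.35 CPM. The change passed edgeR's test at an adjusted p of 1.87e-06. It stood at 130 CPM on 31 August, 3.38 CPM on 2 September and 11.2 CPM on 5 September, and whether the labels of the last 2 dates were exchanged is open. Potri.001G015400 stood at 93.2 ± 33.2 CPM early (SD, n = 4), 5.71 ± 6.31 CPM in the middle period (SD, n = 6) and 0.391 ± 0.229 CPM late (SD, n = 5). Its summed counts of 1506, 139 and 7 gave an early to late ratio of 219, with an exact interval of 106 to 545, and an edgeR log2 change of -7.64 (SE 0.75, adjusted p = 2.41e-06). Without 5 September its middle mean was 3.31 CPM.

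**Figure D2:**
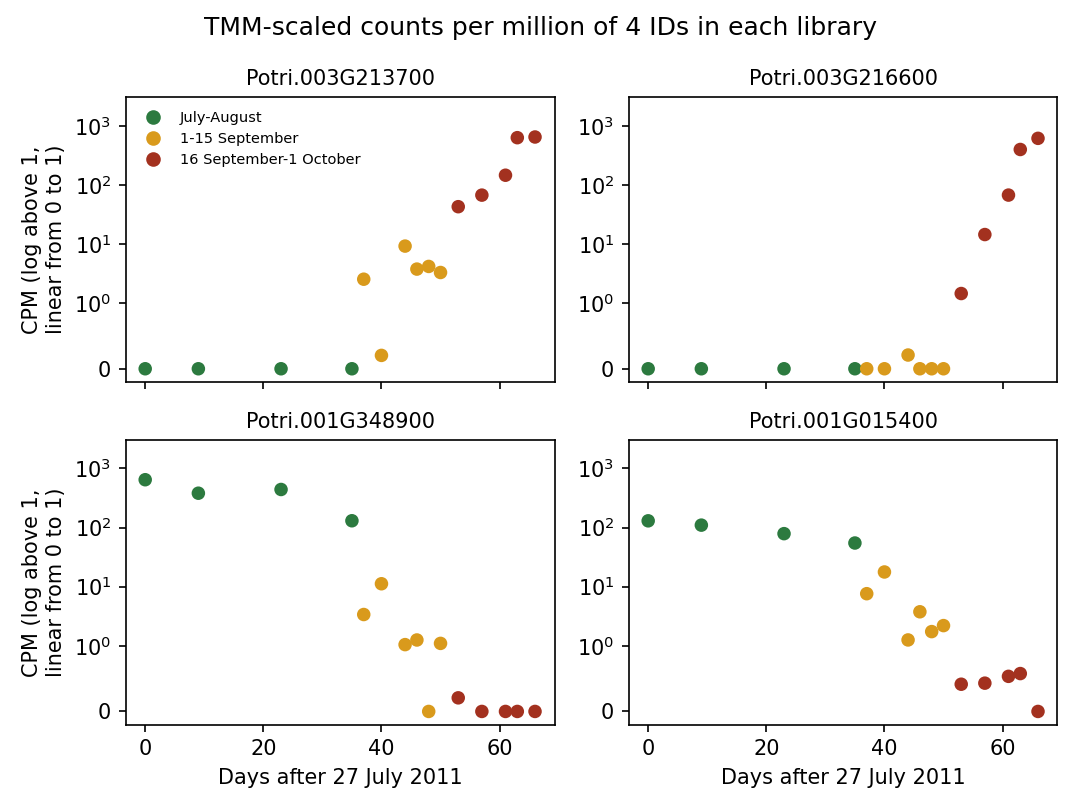
TMM-scaled CPM (y axis, linear from 0 to 1 and logarithmic above) of 4 IDs in each of the 15 libraries against days after 27 July 2011 (x axis), with 1 point per library coloured by period. The upper pair is at 0 in the 4 early libraries and reaches 644 and 611 CPM on 1 October, and the lower pair falls to under 1 CPM in the late libraries.

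A few IDs held a large share of the counts, and that share fell in autumn. What these IDs encode is not given in the sources used here, and nuclear copies of organelle or ribosomal sequence that collect reads were not excluded, so the shares are of counts and not of known genes. Potri.013G140100, the most abundant ID and named after its values were seen, took 49.96 ± 0.44% of the counts early (SD, n = 4), 46.5 ± 2.03% in the middle period (SD, n = 6) and 30.5 ± 13.6% late (SD, n = 5). It fell from 50.5% on 27 July (95% Wilson interval 50.4 to 50.5%) to 37.8% on 26 September (37.7 to 37.8%), 16.8% on 28 September (16.7 to 16.8%) and 14.7% on 1 October (14.6 to 14.8%). The late share was below the early one (exact permutation p = 0.0159, adjusted 0.026) and below the middle one (exact permutation p = 0.00433, adjusted 0.0195), and the middle share was below the early one (exact permutation p = 0.00952, adjusted 0.0245). Neighbouring dates are not independent, so these permutation p-values are too small. The 10 most abundant IDs together held 83.8 ± 0.29%, 77.3 ± 2.26% and 56 ± 19.4% of the counts in the 3 periods, with 37.5% on 28 September and 32.4% on 1 October. They were ranked by summed counts, which favours IDs abundant in the deeper early libraries. The 10 highest IDs of each library held 83.8%, 77.3% and 56.5%. A member, Potri.001G412500, went the other way, from 0.796% on 27 July to 4.34% on 1 October, with an early to late change of 0.44 log2 units after scaling (SE 0.39) that was not past the threshold (adjusted p = 0.349). After TMM scaling, Potri.013G140100 changed by -1.59 log2 units from early to late (SE 0.54, edgeR adjusted p = 0.0175). Of 31 alternatives, 7 ended that call, among them library totals alone with a change of -0.71 (adjusted p = 0.123), and the adjusted p ranged from 2.24e-06 to 0.308.

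**Figure D3:**
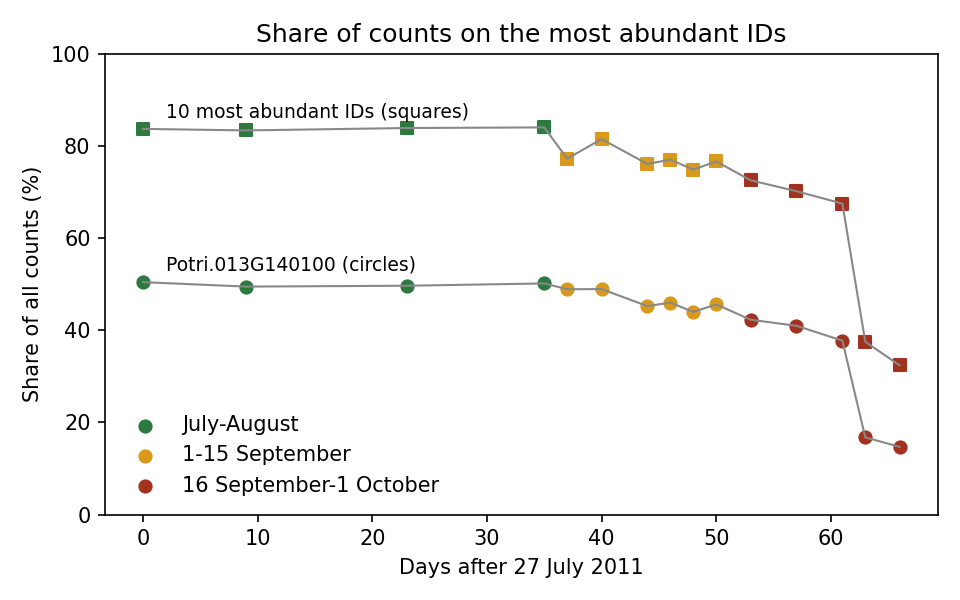
Share of all counts in percent (y axis, from 0 to 100) held by the 10 most abundant IDs (squares) and by Potri.013G140100 alone (circles) in each of the 15 libraries against days after 27 July 2011 (x axis). The share of Potri.013G140100 falls from 50.5% on 27 July to 14.7% on 1 October, with the widest step between 26 and 28 September.

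Of the 10 most abundant IDs, 8 belonged to 2 short runs of neighbouring numbers, 1 under the prefix 013G and 1 under 011G. In the 013G run all 8 tested IDs fell from early to late, with a median log2 change of -2.0, and the run's share of counts went from 72.3 ± 0.48% (SD, n = 4) to 47.1 ± 18.6% (SD, n = 5). In the 011G run all 8 tested IDs fell as well, with a median of -1.63, and the share went from 10.6 ± 0.185% to 6.73 ± 2.31%. With library totals alone, 4 and 3 of the 8 IDs of these runs were still called lower and none higher, and all 16 had changes below 0. How reads shared between such neighbours were counted is not given in the sources used here, so single values within a run are uncertain.

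IDs of different abundance moved in different directions relative to the TMM reference. Among the 10 most abundant, 0 were called higher and 9 lower in late leaves. Of the next 90 IDs, 40 were higher and 37 lower. Of the 900 after those, 500 were higher and 179 lower, and of the following 4000, 1725 were higher and 778 lower. Of the remaining 10583, the least abundant, 2294 were higher and 3506 lower. Relative to the median of all IDs, the medians of these 5 classes were -1.51, 0.45, 0.96, 0.43 and -0.25 log2 units with TMM. With library totals alone the counts of calls became 1 higher and 2 lower in the first class and 4755 higher and 1608 lower in the last.

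From July and August to 1 to 15 September, 709 IDs (4.55%) differed at an adjusted p of 0.05, 376 higher and 333 lower in the middle leaves, by edgeR's quasi-likelihood test. Among them, 355 rose and 315 fell by more than 2-fold. Among the IDs named above, Potri.001G348900 fell by 6.83 log2 units (SE 0.74, adjusted p = 0.000245) and Potri.001G015400 fell by 3.88 (SE 0.53, adjusted p = 0.00114). Without 5 September the first fell by 8.03 and the second fell by 4.75. With period limits 1 date earlier neither was called (adjusted p = 0.106 and 0.0968). These limits move 31 August into the middle period and 15 September into the late one. Potri.003G213700 had 75 counts against 0 (adjusted p = 0.0407), but that call ended without any 1 of the 10 libraries of these periods (adjusted p = 0.059 to 0.119), with limma-voom (0.213), with thinning to 1 depth (0.195) and with period limits 1 date later (0.0837) or earlier (0.283). Potri.003G216600, with 1 count against 0, was not detectable at this depth. Libraries of both periods did not overlap for 10.8% of the IDs, where chance gives 0.952% if every division of the libraries is equally likely. Drift over the dates raises that share too. The count of 709 rested on single libraries, on the period limits and on the late libraries that share the fit. It was 163, 281 and 254 without 27 July, 5 August or 19 August, 459, 284, 337 and 431 without 2, 9, 13 or 15 September, 105 and 100 with period limits 1 date later and earlier, 2229 with the late period left out of the fit and 3797, of them 96.4% higher, with library totals alone.

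From 1 to 15 September to the late leaves, 7440 IDs (47.7%) differed, 3810 higher and 3630 lower, by edgeR's quasi-likelihood test. More than 2-fold changes were found upward for 2917 IDs and downward for 3021, and more than 8-fold changes for 599 and 155. Potri.003G213700 rose by 6.27 log2 units (SE 0.88, adjusted p = 0.000168), and Potri.003G216600 rose from 1 to 1721 counts (adjusted p = 0.000192). Potri.001G015400 fell by 3.76 log2 units (SE 0.75, adjusted p = 0.000885) and Potri.001G348900 fell from 78 counts to 1 (adjusted p = 0.00233). With period limits 1 date later the call of Potri.001G348900 ended (adjusted p = 0.063). These limits move 2 September into the early period and 18 September into the middle one. Without 5 September Potri.001G015400 fell by 2.95, and without 9 September Potri.003G213700 rose by 6.89. Potri.013G140100 had a log2 change of -0.84 (SE 0.49), which was not past the threshold (adjusted p = 0.163). The share of higher IDs among the calls was 51.2% with TMM, 38.2% with the upper quartile and 65.4% with library totals alone. The period is uneven, and without 28 September and 1 October 6061 IDs were called.

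Fewer IDs had a count in late leaves at a given depth. With every library thinned to 164929 counts outside the 10 most abundant IDs, 17507 ± 326 IDs had a count early (SD, n = 4), 17547 ± 243 in the middle period (SD, n = 6) and 15220 ± 1231 late (SD, n = 5). Late leaves were below early ones (exact permutation p = 0.0159, adjusted 0.026) and below middle ones (exact permutation p = 0.00433, adjusted 0.0195), and early and middle leaves did not differ beyond their spread (exact permutation p = 0.8, adjusted 0.825). The number of IDs that together held 50% of these counts was 1175 ± 41.9 early (SD, n = 4), 1548 ± 112 in the middle period (SD, n = 6) and 987 ± 350 late (SD, n = 5). The middle value was above the early one (exact permutation p = 0.00952, adjusted 0.0245) and above the late one (exact permutation p = 0.00433, adjusted 0.0195), while late and early did not differ beyond their spread (exact permutation p = 0.444, adjusted 0.533). Dates next to each other are not independent, so the permutation p-values of both measures are too small. Within the late period, the number of IDs that held 50% was 1278 on 18 September and 1332 on 22 September. It was 1091 on 26 September, 641 on 28 September and 593 on 1 October. Early libraries had 1114 to 1205, so the late dates lay on both sides of them.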

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

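The test of separate collections, those on depth and on the abundant IDs and that of exchanged dates were chosen only after the results they bear on had been seen. In 31 groups of 4 to 6 libraries, a library stood apart from the nearest of the others by Dixon's 95% limit in 4. Chance gives such a gap in about 1 in 20 groups of normally distributed values, a rate that does not hold for counts near 0. All 4 were values of named IDs. Potri.001G015400 was at 0 CPM on 1 October, where the nearest late library had 0.414 CPM, a difference of a few counts. That value lies below the 1 October floor of 2.59 CPM. Potri.001G348900 was at 11.2 CPM on 5 September, from 55 counts, against 3.38 CPM in the nearest middle library, 2 September. Potri.001G348900 was also at 0.207 CPM on 18 September, where the other late libraries had 0, and this is a single count. Potri.003G216600 was at 0.209 CPM on 9 September, also a single count, against 0 in the other middle libraries.

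Counts of 18 and 19 September agreed more closely than sampling allows. A pair of separate collections should scatter by 1 or more relative to binomial sampling. The observed 0.618 lies below this, but it is the value that raised the question and so no separate test. A random subset at 23.8% of the depth should give 0.615, and 0 of 18378 IDs had more counts on 19 than on 18 September, whereas in 33 other pairs of similar depth ratio 3.91% to 38.8% of IDs did. These values are consistent with the reads of 19 September being a part of those of 18 September. Which of the dates the leaves belong to stays open, and no biological explanation was tested.

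The libraries of 28 September and 1 October lay apart from the others. On a component computed without TMM, the gap from 26 to 28 September was 27.9% of the whole range, although those dates are 2 days apart. Low depth was argued against, since the gap was 26.1% with every library at 1 depth. The falling share of the 10 most abundant IDs was also argued against as the whole cause, since the gap was 23.3% without them. The later date itself, leaves of another tree and a separate library preparation stay open and untested, since the labels name neither trees nor batches.

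The library of 2 September lay beyond that of 5 September on the first component, at 17.5% against 9.43% of its range. The 10 most abundant IDs held 84.1% of counts on 31 August, 77.3% on 2 September, 81.5% on 5 September and 76.1% on 9 September. Exchanging the labels of 2 and 5 September shortened the path of rank distances through all dates by 4.19%, the most of 14 exchanges of neighbouring dates. Of the 14, 7 shortened the path, the next by 3.11% (5 and 19 August), and the order had been seen before, so exchanged labels and true variation between days stay open. With both dates exchanged the time course gave 9992 calls against 9807.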

How the results depend on the processing

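The counts of other splits and the alternatives named here as added were chosen only after the results had been seen. Other assignments of the libraries to the dates or periods argued against chance placement of single libraries for all 4 counts. They break up runs of neighbouring dates, so any smooth drift over the dates could give this too. The real assignment was the only 1 of 100 with as many calls for late against early (9068, highest other 4702), middle against early (709, highest other 4), late against middle (7440, highest other 4757) and the time course (9807, highest other 3567). Late against early kept within 1.5 times of its count in 32 of 34 alternatives, late against middle in 31, the time course in 33 and middle against early in 17. A test against 2-fold gave 4769 late against early, 2443 late against middle and 27 middle against early. An adjusted p of 0.01 gave 4837 late against middle and 132 middle against early. Middle against early also moved to 3797 with library totals alone, to 105 and 100 with period limits 1 date later and earlier, and to 1213 with DESeq2. Left-out libraries gave 163 to 1030 calls there, and 8177 to 9109, 6189 to 7818 and 8460 to 10176 for late against early, late against middle and the time course. Of the added alternatives, thinning to 1 depth gave 2876 late against early, 2494 late against middle, 231 middle against early and 3367 in the time course, with 5498 IDs tested in place of 15583. Middle against early gave 1634 without the 4 libraries with the lowest totals, 2245 without 28 September and 1 October and 2229 with only its own periods in the fit. Why these 3 counts were higher was not tested. All 16 libraries gave 8844, 723, 7278 and 10055 calls for late against early, middle against early, late against middle and the time course. The first component kept its rank correlation with the day in 25 alternatives (rho 0.96 to 0.99). From early to late, the 4 IDs named by rule kept direction and call in every alternative that tested them (33, 27, 33 and 33). They were chosen from these same libraries for their largest changes, so this is no separate support. That choice may also overstate their fold changes. Potri.003G216600 was not tested in 6, each without at least 1 late library from 22 September on. Potri.013G140100 kept its direction in 31 alternatives and lost its call in 7, and the cause was not tested. No paired analysis was possible because the labels give no replicate numbers shared between periods. The gene list tests were not run for want of gene names. Depth limits the low IDs most, since the median count of a listed ID was 3 in the shallowest library.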

Other observations

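The tests below, except that of chance placement of the IDs, were chosen only after related values had been seen. Some IDs passed from 0 counts to a count in each library, or the reverse, between the early and the late leaves. With 3872212 and 4620858 counts outside the 10 most abundant IDs, 187 IDs had 0 counts in the 4 early libraries and a count in each of the 5 late ones. In the other direction, 270 IDs had a count in each of the 4 early libraries and 0 counts in the late ones. Of the 126 ways to divide these 9 libraries, 1 gave as many IDs in the second direction (the real one, highest other 86) and 2 did in the first (highest other 197). Without 28 September and 1 October the numbers were 277 and 355, and the highest of the other 34 splits gave 193 and 115. A count of 0 over the early libraries allows up to 3 counts, or 0.189 CPM, so these IDs were not detectable rather than absent.

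IDs with neighbouring numbers changed together from early to late. The hypothesis of a chance placement was tested by shuffling the IDs within their prefix. Over 6768 pairs of tested IDs next to each other in number, the log2 changes had a rank correlation of 0.160 across genes, which are not independent replicates, and the highest of 1000 shuffles gave 0.0392. Chance placement was thus argued against. Among pairs with both members called, 1458 moved the same way and 944 in opposite ways. There were 11 runs of at least 5 neighbours called in 1 direction, against a median of 2 and a highest value of 9 in 200 shuffles, and 5 of the 11 were falling runs under the prefix 013G. Duplicated genes side by side, reads shared between them and shared regulation stay open, since nothing here gives the sequences.

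Under the prefix 013G, 152 of the called IDs were higher and 256 lower in late leaves, so that 37.3% were higher (Fisher's exact test against the other prefixes, adjusted p = 1.38e-06 over 20 prefixes). Without the run that holds the most abundant ID the share was 38.0%. Other falling runs under 013G, some of them close in number to that run, stayed in. A shift of the prefix apart from that stretch was therefore not tested. The share of the whole prefix lay below that of the other prefixes under each scaling. It was 33.4% against 45.5% by relative log expression, 29.0% against 41.3% by the upper quartile and 66.8% against 80.0% by library totals alone. The prefix T went the other way, with 119 higher and 73 lower (62.0% higher, adjusted p = 0.0127), as did 002G, with 356 higher and 285 lower (55.5% higher, adjusted p = 0.0401). Genes are not independent replicates, so these p-values describe the lists and not the plants.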
